A study of Arabidopsis thaliana with 6 samples.

How the data were processed

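Whole seedlings of Arabidopsis thaliana were profiled by RNA sequencing in the Col-0 accession and in a toc1-21 prr5-1 double mutant. Seedlings were 10 days old, had grown in long days at 22 °C on MS medium with 3% sucrose, and were collected at ZT15, that is 15 h after lights on. Each genotype had 3 libraries, which the series' design text calls biological replicates. How the replicates were grown apart is not given in the sources used here, so p-values measure the spread between these samples. Per the labels' protocols, RNA was extracted with Trizol, treated with DNase I and made into libraries with a directional kit.

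The deposited files hold RPKM values (reads per kilobase of gene, scaled to library depth) for 33602 genes, per the file headers, with 1 file for each library. Per the submitters' processing notes, TopHat2, TopHat and edgeR were used with the TAIR10 genome build, with no versions or roles stated. The read counter, its strand setting and its treatment of reads that match several genes are not given in the sources used here. Reads from overlapping or antisense genes therefore cannot be told apart, and values of near-identical genes are uncertain.

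The RPKM values come from whole reads. Low values gave the relative depth of the libraries, and the depth of each library came out as a whole number to within 0.0053. The reads behind the values numbered 14617043, 16199047 and 22173648 in Col-0 replicates 1 to 3 and 20737672, 26792712 and 19956080 in mutant replicates 1 to 3. A gene length that made all 6 values whole to within 0.001 was found for 25139 of 25139 genes with a value above 0. The length taken was the smallest such length, so reads of a gene are too few where its true reads share a common factor. The recovered reads summed to between 99.51% and 99.56% of each depth. At these depths a value of 1 RPKM stood for 14.6 to 26.8 reads in a gene of 1 kb, which limits the precision of genes near the filter. Pairs of libraries within a genotype differed by more than counting noise, with a chi-square per degree of freedom of 5.97 to 21.52, so no pair looked like copies of 1 library. This does not show that the libraries came from separate plants.

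Because the unit is RPKM, the main test was limma with a mean-variance trend on log2(RPKM + 1), with genotype as its only term. Genes with at least 1 RPKM in at least 3 libraries were tested, which left 19710 genes. P-values were adjusted by Benjamini-Hochberg over these genes and called at 0.05. Every log2 fold change is on the log2(RPKM + 1) scale, mutant over Col-0, which understates the change of low genes. The 2-fold limits on called genes use this scale too, while fold values given for single genes are ratios of mean RPKM. In simulated data for this comparison (19710 genes, 3 against 3, 200 genes changed), the test called 59.7% of genes changed 1.5-fold, 91.0% of those changed 2-fold and 100.0% of those changed 4-fold. Of its calls, 7.7% were unchanged genes. Changes were planted only in genes with a Col-0 mean log2(RPKM + 1) above 2, so the shares called do not cover genes that are low in Col-0. The real data gave 2080 called genes, against 200 planted here. The cut-off on p depends on the share of changed genes, so the shares called may not carry over to the real comparison.

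Gene lists for 17 pathways and 7 cell types were fixed before the data were examined, as were the design, the other settings to try and the rule for named genes. The rule takes TOC1, PRR5, PIF4 and PIF5, up to 4 members per list with the smallest adjusted p past 0.05, any list member named as not passing, and the 10 largest changes in each direction. The largest changes needed an adjusted p under 0.05, a mean of at least 2 RPKM and no overlap between the genotypes' values. Lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01 and adjusted over their family. TOC1 and PRR5 are in no list. Of the 293 list genes, 11 carry another name in the reference table and are matched by locus.

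Gene names and positions were looked up by locus in the TAIR10.1 annotation, which matched 97.7% of loci. The files carry no coordinates, and none were converted between builds. Chromosome stretches with many called genes were defined after the data were examined, first from the calls per 1-Mb bin and then with a hidden Markov model of 2 states on calls changed under 2-fold, in gene order. The model was tested on simulated calls at 12% inside and 5% outside planted stretches. With 5 chromosomes (20000 genes, stretches of 1500 genes) it recovered 94.4% of planted genes. In 100 draws of 1 chromosome (4000 genes, a stretch of 1000 genes) it recovered a median of 98.2% and at worst 31.1%, with up to 19.4% of other genes placed inside, so the ends of a stretch are approximate. GO terms of 10 to 500 genes, as the deposited files list them, were tested with a one-sided hypergeometric test against tested genes with a term. Odds ratios come from Fisher's exact test, two-sided, with 95% intervals.

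Other settings tried were no filter, a filter at 5 RPKM, the replicate number as a block, leaving out each library, nuclear genes only, pseudocounts of 0.1 and 5, stricter thresholds, and 3 other forms of the set test. Settings added after the data were examined were limma-voom on recovered reads, median-ratio scaling and the genes outside the stretches. Analyses used R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.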

Results

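Expression was measured in whole seedlings of Col-0 and of the toc1-21 prr5-1 double mutant, with 3 libraries per genotype, all taken at ZT15. TOC1 and PRR5 encode pseudo-response regulators of the circadian clock. The single comparison of the series asks which genes differ when both are mutated, and its title names PIF4 and PIF5, transcription factors of hypocotyl growth, as repressed targets. The libraries rest on 14617043 to 26792712 reads.

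Both mutated genes were lower in the mutant, and PIF4 and PIF5 were higher. TOC1 fell from 33.6 ± 1.49 RPKM (SD, n = 3) to 16.8 ± 1.91 RPKM (SD, n = 3), a log2 fold change of -0.96 (limma adjusted p = 0.000187). PRR5 fell from 2.94 ± 0.0664 RPKM to 1.12 ± 0.216 RPKM (SD, n = 3 each), a log2 fold change of -0.89 (limma adjusted p = 0.00371). Transcripts of both genes were still detected in every mutant library. PIF4 rose from 1.76 ± 0.351 to 5.29 ± 0.359 RPKM (SD, n = 3 each), which is 3.01-fold (limma adjusted p = 0.000468). PIF5 rose from 3.53 ± 0.639 to 13.6 ± 1.44 RPKM (SD, n = 3 each), a log2 fold change of 1.70 (SE 0.137, limma adjusted p = 3.46e-05). On TAIR10.1, TOC1 lies on chromosome 5 at 24674963 to 24678550 and PRR5 on chromosome 5 at 8356204 to 8358546. PIF4 lies on chromosome 2 at 17886101 to 17889087 and PIF5 on chromosome 3 at 21827905 to 21830837. With a pseudocount of 5 the log2 fold changes were smaller, at -0.37 for PRR5, 0.61 for PIF4 and 1.13 for PIF5, with every call kept.

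**Figure D1:**
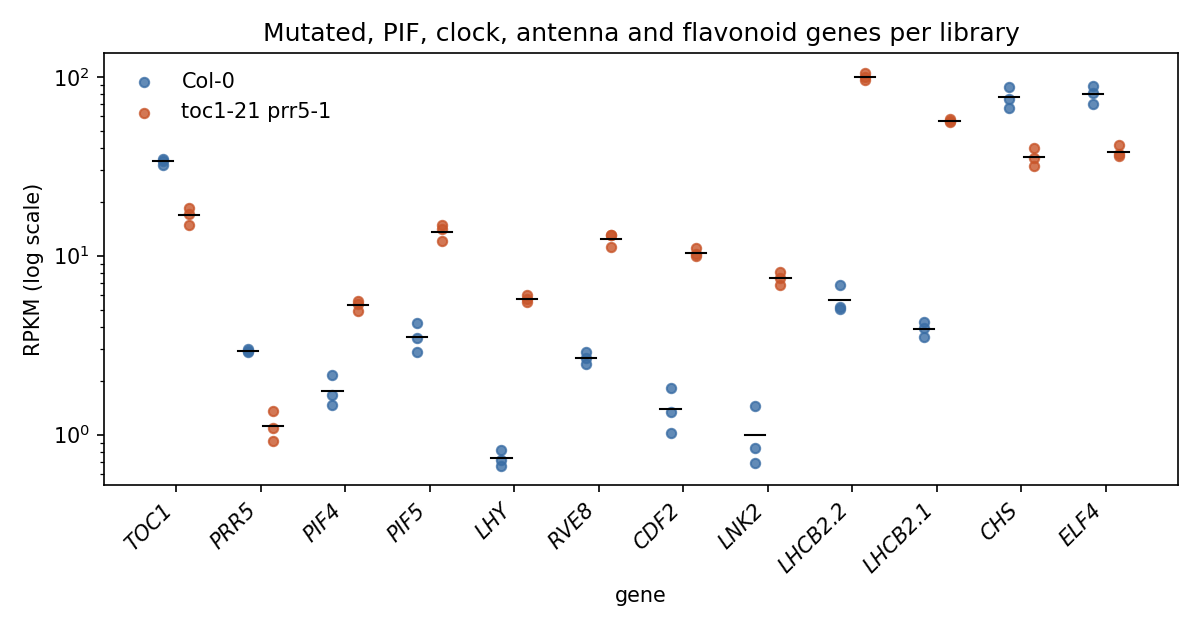
RPKM on a log axis for 12 genes, with a point for each of the 3 libraries of Col-0 (blue) and toc1-21 prr5-1 (orange) and a line at the mean. PIF5 averaged 3.53 RPKM in Col-0 and 13.6 RPKM in the mutant, and the libraries of the genotypes do not overlap for any gene shown.

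Of the 7 genes in the PIF family list, 2 were higher (PIF4 and PIF5), 1 was lower and 4 did not pass, and adjusted over the list alone the counts were 3 higher and 3 lower. PIF7 fell from 3.20 ± 0.0516 to 1.84 ± 0.213 RPKM (SD, n = 3 each, limma adjusted p = 0.0259), a call lost in each of the 6 fits that left out 1 library, at adjusted p between 0.0525 and 0.11. PIF1 was at 9.05 ± 0.712 and 12.2 ± 1.52 RPKM (SD, n = 3 each) and did not pass (limma adjusted p = 0.0617). The list as a whole did not pass camera (adjusted p = 0.246).

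Clock genes that normally peak in the morning or by day were higher in the mutant at ZT15. LHY, a morning-expressed MYB repressor, rose from 0.740 ± 0.0788 to 5.74 ± 0.264 RPKM (SD, n = 3 each, log2 fold change 1.95). RVE8, an activator of evening genes, rose 4.62-fold to 12.4 ± 1.06 RPKM (SD, n = 3). CDF2, a repressor of CONSTANS, rose 7.49-fold and LNK2, a partner of RVE8, 7.54-fold. Of the 14 tested members of this list, 11 were higher, none lower and 3 did not pass, and adjusted over the list alone 12 were higher. The list passed camera (adjusted p = 6.76e-15), with adjusted p = 0.0514 with an estimated correlation. CCA1, the closest relative of LHY, was below the filter and not tested, at 0.0971 ± 0.0503 RPKM in Col-0 and 0.880 ± 0.136 RPKM in the mutant (SD, n = 3 each).

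Evening-phased clock genes went both ways. ELF4, a subunit of the evening complex, fell from 80.0 ± 8.94 to 38.2 ± 3.16 RPKM (SD, n = 3 each, log2 fold change -1.05). BOA, a homolog of LUX, fell from 19.8 ± 1.83 to 11.3 ± 1.09 RPKM, and the blue-light receptor FKF1 from 8.06 ± 1.66 to 3.89 ± 0.390 RPKM (SD, n = 3 each). PRR3, a further pseudo-response regulator, rose from 4.71 ± 0.627 to 10.97 ± 0.972 RPKM (SD, n = 3 each). Among 11 tested members 1 was higher, 4 were lower and 6 did not pass, with the same counts adjusted over the list alone. The list did not pass camera (adjusted p = 0.277). Outside 6 chromosome stretches described further on, 7 members were tested, of which 0 were higher and 1 was lower.

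Genes for the light-harvesting antenna, which binds chlorophyll at the photosystems, were mostly higher in the mutant. LHCB2.2 rose from 5.67 ± 1.03 to 100.3 ± 4.61 RPKM and LHCB2.1 from 3.92 ± 0.378 to 56.9 ± 1.35 RPKM (SD, n = 3 each), log2 fold changes of 3.94 and 3.56. LHCB1.1 rose 7.60-fold to 80.4 ± 6.71 RPKM (SD, n = 3), and LHCB1.3, the most abundant member, rose from 2848 ± 133.8 to 7597 ± 881.9 RPKM (SD, n = 3 each). Of 17 tested members, 12 were higher, 1 was lower and 4 did not pass, and adjusted over the list alone 13 were higher and 1 lower. The member that fell was LHCB4.2, from 67.9 ± 5.10 to 11.3 ± 1.70 RPKM (SD, n = 3 each, log2 fold change -2.49). The list passed camera (adjusted p = 9.34e-15), with adjusted p = 0.0886 with an estimated correlation. LHCB1.1, LHCB1.2 and LHCB1.3 are near-identical, as are LHCB2.1 and LHCB2.2, so the value of each gene is uncertain. Summed over the family, LHCB1 reads rose 2.51-fold and LHCB2 reads 13.6-fold.

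Most of the growth and auxin genes did not pass. HFR1, a light-signalling bHLH factor, rose from 9.90 ± 1.23 to 22.7 ± 1.33 RPKM and IAA29, an auxin-response repressor, from 2.79 ± 0.254 to 5.53 ± 0.361 RPKM (SD, n = 3 each). Of 17 tested members of the PIF-induced and shade-induced list, 3 were higher and 14 did not pass, and adjusted over the list alone 5 were higher. ATHB2 (7.32 ± 2.62 and 11.4 ± 0.817 RPKM), YUC8 (2.06 ± 0.293 and 3.02 ± 0.865 RPKM) and YUC9 (1.93 ± 0.402 and 3.00 ± 0.698 RPKM; SD, n = 3 each) did not pass. The list passed camera (adjusted p = 0.0300), with adjusted p = 0.487 with an estimated correlation, and lost its call without Col-0 replicate 3 (adjusted p = 0.115) and without mutant replicate 3 (adjusted p = 0.0570), with fry (adjusted p = 0.0618) and on ranks (adjusted p = 0.0839). It also lost its call among the genes outside 6 chromosome stretches described further on (adjusted p = 0.915).

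In the early auxin response list, 5 of 17 tested genes were higher, 12 did not pass, and adjusted over the list alone 7 were higher. Camera gave adjusted p = 0.00125, and adjusted p = 0.247 with an estimated correlation. Among expansins and XTHs, enzymes and proteins of wall loosening, XTH24 rose from 68.8 ± 6.28 to 118.1 ± 15.3 RPKM and XTH4 from 381.7 ± 23.1 to 606.0 ± 69.0 RPKM (SD, n = 3 each). EXPA1 fell from 224.8 ± 7.62 to 163.5 ± 6.82 RPKM (SD, n = 3 each). Of 19 tested genes 4 were higher, 1 was lower and 14 did not pass, with the same counts adjusted over the list alone. Camera gave adjusted p = 0.0300, and adjusted p = 0.487 with an estimated correlation. The call was lost without Col-0 replicate 1 (adjusted p = 0.0796), Col-0 replicate 3 (0.0583), mutant replicate 2 (0.111) or mutant replicate 3 (0.0598), with fry (0.161) and on ranks (0.0518).

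Flavonoid and anthocyanin genes were lower in the mutant. CHS, the entry enzyme of the pathway, fell from 76.6 ± 10.5 to 35.7 ± 4.18 RPKM, F3H from 18.4 ± 3.49 to 6.20 ± 0.394 RPKM and F3'H from 5.15 ± 0.450 to 1.61 ± 0.432 RPKM (SD, n = 3 each). FLS1, which makes flavonols, fell from 21.6 ± 1.84 to 8.35 ± 2.21 RPKM (SD, n = 3 each). Of 10 tested members, 8 were lower and 2 did not pass, and adjusted over the list alone 9 were lower. The list passed camera (adjusted p = 9.38e-09), with adjusted p = 0.247 with an estimated correlation. The regulators PAP1, PAP2 and TT8 were below the filter and not tested.

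Starch metabolism genes went both ways, with more of the called genes lower than higher. ISA3, a debranching enzyme, fell from 27.8 ± 4.25 to 17.5 ± 0.430 RPKM, DPE1 from 28.8 ± 0.303 to 20.9 ± 0.595 RPKM and PHS1 from 51.4 ± 4.04 to 36.5 ± 2.85 RPKM (SD, n = 3 each). The amylase AMY3 rose from 15.7 ± 1.43 to 24.0 ± 3.01 RPKM (SD, n = 3 each). Of 14 tested members, 6 were lower, 1 was higher and 7 did not pass, and adjusted over the list alone 8 were lower and 2 higher. The list passed camera (adjusted p = 0.00673), with adjusted p = 0.487 with an estimated correlation and 0.0650 with fry.

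Of the photoperiodic flowering list, FLC, a repressor of flowering, rose from 5.74 ± 0.474 to 12.6 ± 0.896 RPKM, SPL3 from 8.98 ± 0.644 to 16.6 ± 0.838 RPKM and SVP from 46.4 ± 1.13 to 74.9 ± 6.17 RPKM (SD, n = 3 each). Among 7 tested members 3 were higher, 1 was lower and 3 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.0649). A call appeared without Col-0 replicate 2 (adjusted p = 0.0337), mutant replicate 1 (0.0447) or mutant replicate 2 (0.0468). It also appeared with a filter at 5 RPKM (0.00539) and with fry (0.0303), but not with an estimated correlation (0.487) or on ranks (0.465). Heat shock genes had 2 higher of 6 tested, and 3 adjusted over the list alone. Their camera adjusted p was 0.0366, or an adjusted p of 0.487 with an estimated correlation. That call was lost without Col-0 replicate 2 (adjusted p = 0.0580), Col-0 replicate 3 (0.123) or mutant replicate 1 (0.115), with no filter (0.0643), with fry (0.122) and on ranks (0.0595).

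The remaining pathway lists did not pass camera on log2(RPKM + 1) with genotype as the only term and all 6 libraries. Without mutant replicate 3 the gibberellin list (adjusted p = 0.0400) and the abscisic acid list (adjusted p = 0.0225) passed. The abscisic acid list also passed with limma-voom (adjusted p = 0.0483). With all 6 libraries and an estimated correlation, each of these 2 lists had adjusted p = 0.487. GA3OX2, of gibberellin synthesis, fell from 1.98 ± 0.635 to 0.404 ± 0.226 RPKM (SD, n = 3 each), as the 1 called gene of 14 in its list (camera adjusted p = 0.154, 1 adjusted over the list alone). BR6OX2, of brassinosteroid synthesis, rose from 8.19 ± 1.45 to 15.6 ± 0.657 RPKM (SD, n = 3 each), 1 of 2 higher among 8 (adjusted p = 0.183, 2 adjusted over the list alone). HAI1, an abscisic acid phosphatase, fell from 16.4 ± 3.14 to 8.11 ± 1.36 RPKM (SD, n = 3 each) in a list with 2 lower and 1 higher of 11 (adjusted p = 0.0649, 5 lower and 2 higher adjusted over the list alone). Cold-regulated genes had 2 higher and 1 lower of 9 (adjusted p = 0.616, 2 and 2 adjusted over the list alone). Sugar starvation genes had 1 higher, DIN10, and 1 lower, EXL2, of 9 (adjusted p = 0.451, 2 and 1 adjusted over the list alone). Of the 11 salicylate and defence genes 6 were tested, and 0 of these were called by limma or by limma-voom. Adjusted over the list alone 0 were called, and 1 had an unadjusted p under 0.05 (camera adjusted p = 0.855). Wider defence terms are described further on.

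**Figure D2:**
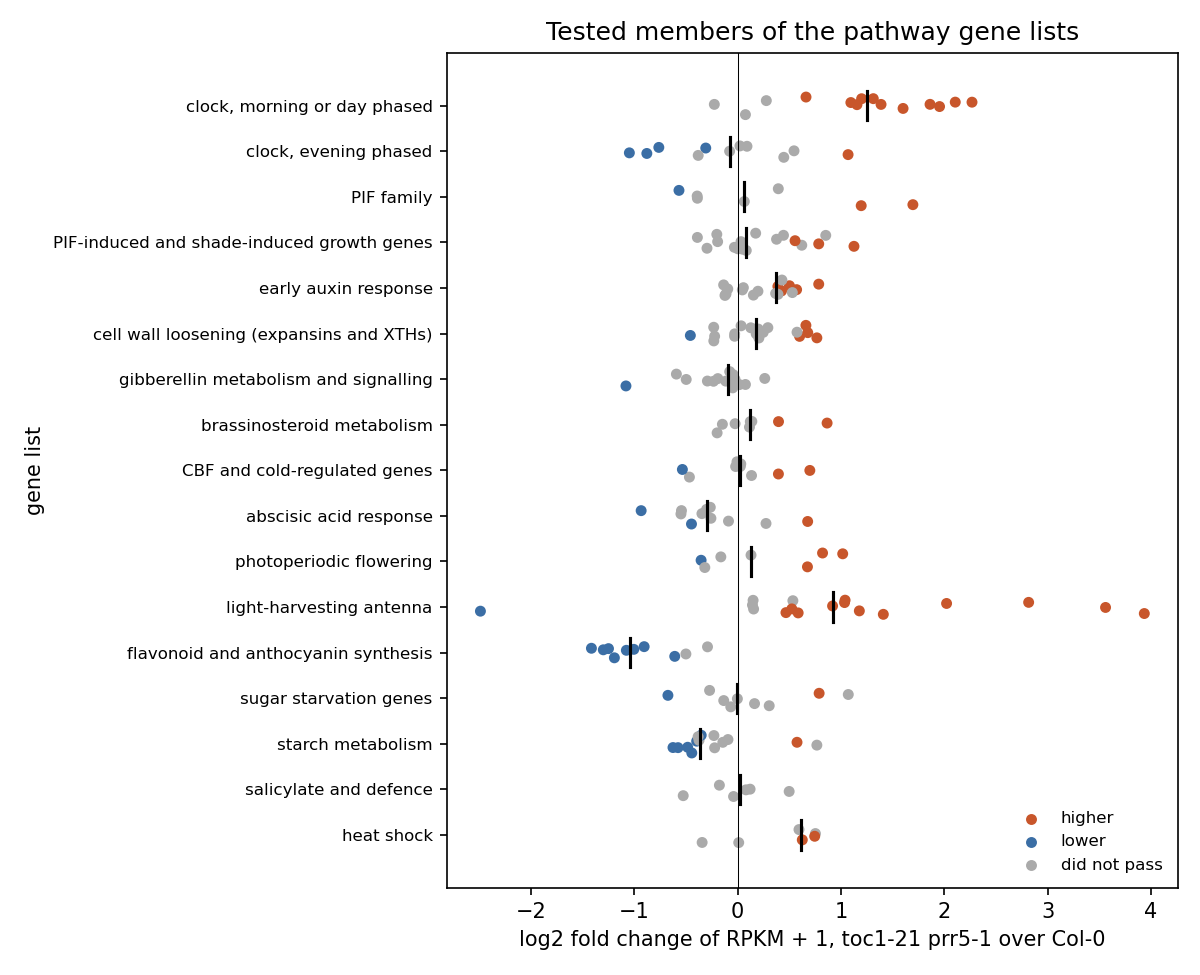
Log2 fold change (toc1-21 prr5-1 over Col-0, RPKM + 1) of each tested member of the 17 pathway lists, coloured by the limma call, with a line at the list's median. The morning clock list has its median at 1.26, the antenna list at 0.92 and the flavonoid list at -1.04.

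Over all 19710 tested genes, 2080 differed between the genotypes, 769 of them higher and 1311 lower in the mutant. A change of at least 2-fold on the RPKM + 1 scale, which understates changes of low genes, was seen for 161 higher and 402 lower genes. The genotypes' values did not overlap for 27.0% of tested genes, where chance gives 10%. The count of called genes fell to 1222 without Col-0 replicate 1, 1294 without mutant replicate 1 and 1313 without mutant replicate 2.

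The largest increases were those of AT4G24420, from 0.596 ± 0.412 to 34.8 ± 1.95 RPKM, and AT3G28320, from 0.155 ± 0.192 to 22.5 ± 1.62 RPKM (SD, n = 3 each), followed by LHCB2.2 and LHCB2.1. Also among the 10 largest were the B-box factor genes STO (4.04 ± 0.690 to 41.3 ± 2.96 RPKM) and STH (0.763 ± 0.233 to 11.6 ± 1.08 RPKM; SD, n = 3 each). NDA1, a mitochondrial NAD(P)H dehydrogenase, rose from 1.96 ± 0.383 to 33.4 ± 2.88 RPKM and PHT4;1, a chloroplast phosphate transporter, from 2.41 ± 0.0198 to 23.8 ± 1.77 RPKM (SD, n = 3 each). AT1G12340 and AT1G78860 complete the 10. The largest decreases were AT1G67865, from 214.5 ± 42.5 to 2.95 ± 0.638 RPKM, and the lectin gene JAL33, from 278.0 ± 19.5 to 5.01 ± 0.111 RPKM (SD, n = 3 each). The others were AT3G06125, AT3G43740, AT3G44798, AT3G44590, AT3G24927, AT4G19500, AT3G18535 and the snoRNA gene AT1G75163, which is listed at 0 in all 3 mutant libraries.

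The called genes were unevenly placed. A model drawn after the data were examined placed 6 stretches with many calls, on TAIR10.1 chromosome 1 (0.00 to 6.56 Mb and 25.21 to 30.42 Mb), chromosome 2 (13.12 to 19.70 Mb), chromosome 3 (0.01 to 16.76 Mb), chromosome 4 (8.75 to 17.46 Mb) and chromosome 5 (23.57 to 26.97 Mb, holding TOC1). In these stretches 1472 of 9169 tested genes were called (16.1%), 449 higher and 1023 lower. Elsewhere 603 of 10395 were called (5.8%), 318 higher and 285 lower. PIF4, LHY, RVE8, ELF4 and LHCB4.2 lie in the stretches, as do all of the 10 largest decreases and 7 of the 10 largest increases. PIF5, PRR5, LNK2, CDF2, LHCB2.1, LHCB2.2, CHS, F3H and FLS1 lie outside. Outside the stretches, 7 of 9 tested morning clock genes and 10 of 12 antenna genes were higher and 7 of 8 flavonoid genes lower, and these 3 lists passed camera there (adjusted p = 2.09e-14, 4.74e-23 and 4.12e-13). With an estimated correlation the adjusted p there were 0.0251, 0.0251 and 0.109, so that the flavonoid list lost its call. The stretches were drawn to gather calls of this comparison, which leaves fewer calls among the genes outside. Camera sets a list against those genes, so its p-values there are not independent support.

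**Figure D3:**
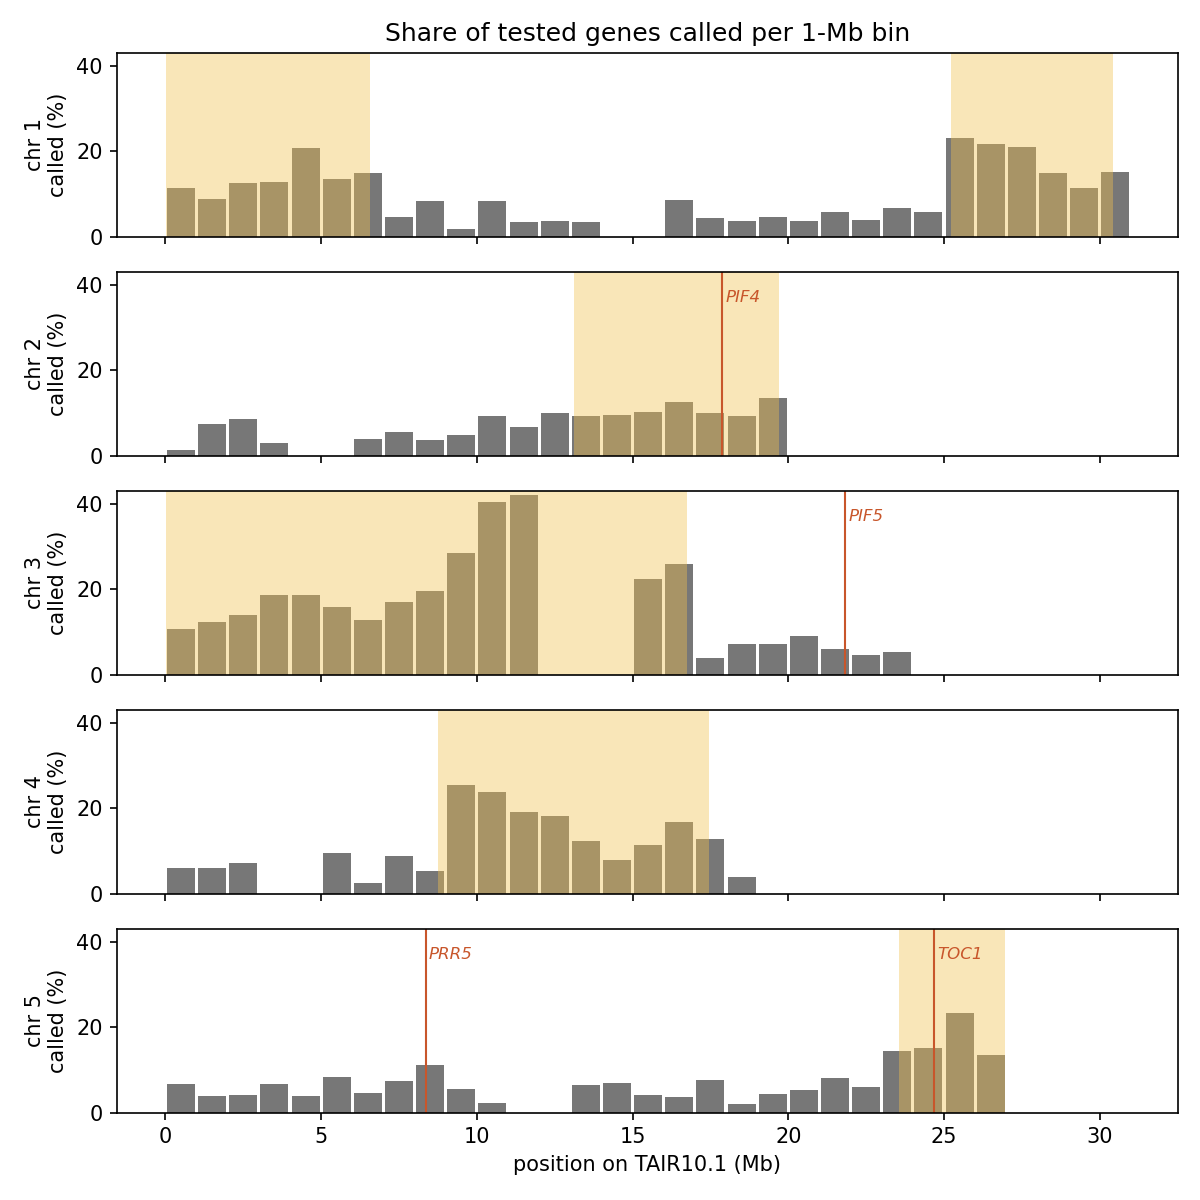
Percentage of tested genes called per 1-Mb bin along the 5 chromosomes (TAIR10.1, Mb), drawn for bins with at least 20 tested genes; shading marks the 6 stretches and lines mark TOC1, PRR5, PIF4 and PIF5. The stretches together hold 70.9% of the called nuclear genes and 46.9% of those tested.

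Among markers of organs and cell types, the seed list had the most lower genes. The seed storage gene CRA1 fell from 356.5 ± 66.6 to 168.2 ± 19.1 RPKM and CRC from 190.8 ± 3.23 to 106.6 ± 14.9 RPKM (SD, n = 3 each). Of 9 tested seed and embryo genes 5 were lower and 4 did not pass, with 5 also adjusted over the list alone (camera adjusted p = 7.03e-05, and adjusted p = 0.264 with an estimated correlation). Mesophyll and shoot genes had 2 higher and 1 lower of 10 (camera adjusted p = 0.854, 2 and 2 adjusted over the list alone). Mitotic genes had 2 lower of 9 (adjusted p = 0.0544, 2 adjusted over the list alone), and 1 of 4 tested meristem genes, too few for camera, was higher (1 adjusted over the list alone). By limma 0 of 8 root hair, 0 of 9 endodermis and 0 of 10 guard cell genes were called, with 0, 2 and 2 at an unadjusted p under 0.05 and 0, 1 and 1 by limma-voom. Adjusted over the list alone, only the endodermis list had calls among these 3, with 1 higher and 1 lower. Their camera adjusted p were 0.0544, 0.837 and 0.458. The root hair list had a median log2 fold change of 0.45 and the mitotic list one of -0.13, and on ranks both passed camera (adjusted p = 0.0157 and 0.0198), with adjusted p = 0.892 for each with an estimated correlation. The root hair gene RHS19 stood at 5.15 RPKM in Col-0 replicate 3, against 17.8 and 19.5 RPKM in the other Col-0 libraries.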

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

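Whether the replicate numbers pair the samples is not given in the sources used here. Deviations of same-numbered libraries correlated at -0.03, 0.15 and 0.04, and not every library correlated best with its own number. With 3 libraries per genotype these values cannot exclude pairing. With the replicate block the count of called genes was 2114 in place of 2080, and the abscisic acid list passed camera (adjusted p = 0.0494). Without the block that list did not pass with an estimated correlation (adjusted p = 0.487), with fry (0.157) or on ranks (0.0518). The directions and calls of TOC1, PRR5, PIF4 and PIF5 held in every alternative fit that tested them, at an adjusted p of 0.05, with log2 fold changes of -1.03 to -0.83, -1.42 to -0.37, 0.61 to 1.62 and 1.13 to 1.99. PIF4, PRR5 and TOC1 have no value in some alternatives, since PIF4 and PRR5 fail the filter at 5 RPKM, and TOC1 and PIF4 lie in the stretches. Leaving out 1 library gave 1222 to 2085 called genes, 406 to 791 higher, 735 to 1302 lower and 5 to 8 pathway lists past camera, in place of 8. Fewer samples were fitted there. The 2-fold minimum, taken on the RPKM + 1 scale, would leave out TOC1 and PRR5, at log2 fold changes of -0.96 and -0.89. A threshold of 0.01 left 1145 genes (396 higher, 749 lower), and a 2-fold minimum 563 (161 higher, 402 lower). Fry and camera on ranks each passed 5 lists, and camera with an estimated correlation passed 0. For the 8 lists past the main test the estimated correlations ran from 0.063 (morning clock) to 0.513 (flavonoid), all above the preset 0.01. A higher correlation makes camera more cautious. Other causes, and the cause of the lower counts with fry and on ranks, were not tested. Chosen after the data were seen, the fit to genes outside the 6 stretches called 453 (249 higher, 204 lower), from 10395 genes tested, and passed 2 lists with an estimated correlation; limma-voom on recovered reads called 2232. For 87 other genes, taken by the naming rule or from enriched terms, 1104 of 1208 gene and fit pairs kept direction and call. In 104 pairs the call was lost, and 0 reversed. These genes were mostly picked from the called ones, so high retention follows in part from the choice. With TOC1, PRR5, PIF4 and PIF5 included, 19 of 91 genes lost their call in some fit that left out 1 library. The planned count tools and their normalizations were not run, since the values are RPKM. Depth limits genes near 1 RPKM.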

Other observations

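The GO tests, the tests of the stretches and the tests on antenna and morning clock genes were chosen after the results were seen; the tests of the mutated loci, of promoter motifs and of other splits were set before. Beyond the fixed lists, genes of chlorophyll synthesis were over-represented among those higher in the mutant, with 10 of 38 called against 1.65 by chance (hypergeometric adjusted p = 0.000464). GUN5, the large subunit of magnesium chelatase, rose from 37.7 ± 2.52 to 175.9 ± 10.9 RPKM, and CH1, chlorophyllide a oxygenase, from 5.28 ± 1.28 to 34.2 ± 2.02 RPKM (SD, n = 3 each). PORB rose from 164.8 ± 8.74 to 407.9 ± 5.92 RPKM and HEMA1 from 68.1 ± 1.18 to 137.3 ± 3.99 RPKM (SD, n = 3 each). Glucosinolate synthesis genes were over-represented there too, with 13 of 28 called against 1.22 by chance (hypergeometric adjusted p = 7.79e-09). Outside the stretches 8 of 15 were called (hypergeometric adjusted p = 1.05e-06). The background there holds fewer calls because of how the stretches were drawn. IMS2, of methionine chain elongation, rose from 33.2 ± 2.78 to 83.0 ± 4.95 RPKM and IPMI1 from 22.5 ± 0.563 to 37.2 ± 0.422 RPKM (SD, n = 3 each). These genes, and those of the following term, were named after their values were seen.

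Genes of oxylipin synthesis were over-represented among lower genes, with 10 of 21 called against 1.39 by chance (adjusted p = 6.08e-05). The lipoxygenase gene LOX2 fell from 106.7 ± 18.6 to 41.2 ± 3.01 RPKM and LOX6 from 14.2 ± 0.716 to 2.68 ± 0.330 RPKM (SD, n = 3 each). Both lie in the stretches, as do 7 of the 10 called members. Outside the stretches 3 of 7 members were called, and with fewer than 10 genes there the term was too small to be tested. Lower genes were also rich in response to wounding (28 of 137 called against 9.06 by chance, hypergeometric adjusted p = 4.36e-05). The same held for defence response to bacterium (32 of 222 against 14.68, adjusted p = 0.00322). Of these calls 23 and 27 lay in the stretches, and outside them neither term passed.

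Called genes changed under 2-fold, 1513 of the 19002 genes used, clustered along the chromosomes, with a log-likelihood gain of the stretches of 134.6, against at most 6.7 in 100 permutations within expression deciles, which argues against expression level as the cause. Genes lost or gained 10-fold, left out when the stretches were drawn, lay in them in 58 of 63 cases, against 46.7% of other genes (odds ratio 13.2, 95% interval 5.4 to 42.3, Fisher's exact p = 3.13e-14). A candidate explanation of the clustering is strain variants, that is DNA of another accession in these parts of the mutant genome. Such DNA may change expression or keep reads from matching the Col-0 reference. The stretches differed, however. That on chromosome 3 held 28 lost and 3 gained genes. That on chromosome 2, which holds PIF4, held 0 lost and 1 gained among 1448 tested genes. Its call rate was 10.5%, against 10.6% of all nuclear genes and 5.8% outside the stretches. The pooled odds ratio therefore says little about the chromosome 2 stretch. Within 2 Mb of TOC1 or PRR5 the odds ratio was 1.21 (1.02 to 1.41), below the 1.5 set beforehand for DNA carried along with both loci. Around TOC1 alone it was 1.62 (1.34 to 1.95, Fisher's exact p = 1.07e-06), and around PRR5 alone 0.68 (0.49 to 0.91). The genes elsewhere include the other stretches, so the pooled value cannot count against DNA carried along with TOC1. The 10 splits of the libraries into 3 and 3 are too few for a share under 0.05; the real split called 2080 genes, the highest other 0, and 1 split reached the real count.

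Higher antenna genes were weighed against 3 technical explanations. Reads shared out among paralogs would leave family sums level, but the smaller ratio, that of LHCB1, was 2.51. If reads that match several genes were dropped instead, the sums need not stay level. The treatment of such reads is not given, so the sums cannot decide that case. Strain variants acting on the genes of the stretches alone would leave members elsewhere level. Outside the stretches, however, 10 of 12 (83.3%) were higher. The share was 3.0% among other genes there, a value lowered by drawing the stretches from the calls. A larger share of leaf tissue would raise mesophyll genes alike. Their median log2 fold change was 0.03 ± 0.36 (SD over 10 genes), against 0.92 for the antenna list. Among higher genes, however, the GO term photosynthesis was over-represented, with 29 of 100 called against 4.35 by chance (hypergeometric adjusted p = 6.84e-14). The 10 mesophyll genes alone therefore do not settle the share of leaf tissue. Variants in the stretches that act on genes elsewhere, for example through a regulator, were not tested and stay open beside an effect of the mutations, which is a hypothesis.

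Of the morning clock genes outside the stretches, 7 of 9 (77.8%) were higher. The share was 3.0% among other genes there, again lowered by how the stretches were drawn. The rise of 7 of these 9 members argues against strain variants acting on the genes of the stretches alone. Variants acting on genes elsewhere stay open for these members too. For members inside the stretches, such as LHY and RVE8, variants of either kind stay open. The same holds for evening clock genes inside the stretches, among them PRR3 and ELF4. For PIF4, which lies inside, variants of either kind stay open as well. For PIF5, which lies outside, variants acting on genes elsewhere stay open. Since 1 time point was sampled, a change in level and a shift in phase stay open for all of these genes. This limit of a single time point covers the antenna, chlorophyll and flavonoid genes too. Genes higher in the mutant had an evening element (AAAATATCT) or a G-box (CACGTG) in the 500 bases upstream in 17.3% of cases, against 14.2% of other genes (odds ratio 1.27, 95% interval 1.04 to 1.54, Fisher's exact p = 0.0154). The G-box alone gave 1.4 and the evening element alone 0.94 (95% interval 0.63 to 1.34). Lower genes gave 1.36 for either motif, 1.34 for the G-box and 1.32 for the evening element (95% interval 1.02 to 1.69). The G-box excess was thus seen in both directions. For the evening element the intervals of higher and lower genes overlap, and a difference between the directions was not tested. Outside the stretches, higher genes gave 1.74 for the G-box (1.25 to 2.37) and 1.18 for the evening element (0.67 to 1.94). Lower genes were not tested for motifs there.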
